A study of Mus musculus with 4 samples.

How the data were processed

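Gene expression was measured in 4 single mouse embryos of the C57BL/6 background at embryonic day 5.5, when the embryo is an egg cylinder of epiblast, extraembryonic ectoderm and visceral endoderm. Mettl14 encodes the partner subunit of Mettl3 in the complex that writes N6-methyladenosine (m6A) on RNA. Each library came from 1 whole embryo. Per the labels' protocols, polyadenylated RNA was amplified with a Smart-Seq v4 kit and sequenced as paired reads of 150 bases. Per the labels' protocols, the genotype was assigned after sequencing by qPCR for Mettl14 on part of the same amplified cDNA. Embryos with Mettl14 mRNA were taken as controls. Expression of the gene alone may not separate homozygous from heterozygous controls, and the level of this gene is not independent evidence of the genotype. The groups are called WT (2 embryos) and KO (2 embryos) here. The part of the gene that was deleted is not given in the sources used here.

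The values are read counts per gene, deposited by the authors as whole numbers without normalisation. TopHat, Cufflinks and the build mm10 are named without version or role, per the submitters' processing notes. The counting program, its strand setting and the gene annotation are not given in the sources used here. Smart-Seq does not mark the strand of origin, so reads of overlapping genes on opposite strands cannot be told apart, and members of near-identical families share reads. The table held 47885 rows, of which 46574 had an Ensembl identifier found in GENCODE M21. Another 816 were gene models without an Ensembl identifier and 495 identifiers were not found. Coordinates, exon structures and symbols were taken from GENCODE M21 on the mm10 sequence.

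Total counts were 16108062 and 20121289 in WT replicates 1 and 2, and 20248636 and 28698541 in KO replicates 1 and 2. A single count equalled 0.059, 0.0534, 0.0472 and 0.0359 CPM (counts scaled to the library size) in these libraries. A gene with 0 counts in both libraries of a group could reach 3 counts over the group, or 0.084 CPM in WT and 0.061 CPM in KO; lower bounds on folds used this floor. It covers counting error only, since amplified reads are not independent molecules.

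KO was compared with WT by edgeR (version 4.0.16, R 4.3.3) with filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust dispersions and the quasi-likelihood F test. Adjustment followed Benjamini and Hochberg over the 15563 genes that passed the filter, with a threshold of 0.05. Fold changes are KO over WT on the log2 scale. Their standard errors (SE) were derived as the absolute log2 fold change divided by the square root of the F statistic. The SE thus restates the F test, and is a poor guide to the uncertainty of a fold where a group has near 0 counts. The 2 embryos of a group were separate animals, and the p-values measure the spread between these 4 embryos. Before the data were examined, 31 gene lists were fixed for the m6A machinery, states of pluripotency, embryonic and extraembryonic lineages, maternal tissue, stress and signalling. Lists were tested with camera in limma (version 3.58.1) on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with an estimated correlation, and with fry. Under limma-voom camera ran on the weighted voom values, and under DESeq2 on its Wald statistics, a form set after first results in which both had repeated camera on log2 CPM. Adjustment ran over the 29 lists with at least 3 tested members. The two-cell-like list had 0 tested members, and the sex-linked list had 2.

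The genes named were also set by a rule written before the data were examined. It took every m6A machinery gene, the 12 genes per direction with the smallest unadjusted p, and up to 4 members of each list with the smallest unadjusted p. The 12 per direction stood in for genes past the threshold because fewer than 10 passed. They had to separate the 2 groups and reach a mean of 5 CPM in the higher group. Predicted genes, pseudogenes and genes of the sex-linked marker and mitochondrial lists were left out of that part. Of the 12 lower genes, 1 is counted in the totals but not reported here.

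The tests were tried on simulated data with the real means, library sizes and dispersions of the 15563 genes, 200 of them changed, in 5 draws. In this simulated KO against WT comparison edgeR recovered 2% of genes changed by 1 log2 unit, 35.2% of those changed by 2, 59.2% by 3 and 75.2% by 4. It made 9.6 false calls per draw on average. DESeq2 recovered 5.6%, 50.8%, 66.4% and 79.2%, with 37.4 false calls per draw. A visceral endoderm list shifted by -1.5 was called in 5 of 5 draws with the preset correlation and in 0 with an estimated one. The simulated genes varied independently of each other, while the members of the real list had an estimated correlation of 0.766. These draws therefore cannot show whether the preset correlation is adequate for the real lists.

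Alternatives fixed in advance were DESeq2 (version 1.42.0), limma-voom, RLE scaling, scaling by library totals, no low-count filter, at least 50 counts in 2 libraries, the replicate number as a block, and each library left out in turn. Removal of each library's trend on GC content and length, with and without the block, was added after the data were seen. With 1 library left out, the lone embryo of a group is assumed to vary like those of the other group.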

Results

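Whole-embryo transcriptomes were compared between 2 embryos classed as Mettl14 knockout (KO) and 2 embryos classed as controls because they expressed it (WT) at embryonic day 5.5. The study asked how loss of Mettl14 affects the maturation of the epiblast, the tissue that forms the embryo proper, at a stage when mutants could not be told from littermates by shape. Depth ran from 16108062 counts in WT replicate 1 to 28698541 in KO replicate 2, and between 18346 and 21488 genes had at least 1 count. Over the genes tested, Pearson correlations of log2 CPM ran from 0.879 for WT replicate 1 with KO replicate 2 to 0.943 between the WT embryos, and the KO embryos correlated at 0.923. KO replicate 1 correlated about as well with the WT embryos (0.93 and 0.925; Spearman 0.946 and 0.942) as with KO replicate 2 (Spearman 0.944), also with no low-count filter (Pearson 0.949 and 0.951 against 0.949). The first principal component held 53.3% of the variance, with KO replicate 2 at 109 and the other 3 embryos between -77.8 and -5.49.

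Mettl14 (ENSMUSG00000028114, chromosome 3, 123368297 to 123386108 on mm10) stood at 34.0 and 31.6 CPM in the WT embryos and at 4.63 and 8.04 CPM in the KO embryos. The log2 fold change was -2.37 (SE 0.45, n = 2 per group), with an edgeR adjusted p of 0.27 and a DESeq2 adjusted p of 0.00042. In the rest of the m6A machinery, Wtap, the adaptor of the writer complex, had 108 ± 38.8 CPM in WT and 43.2 ± 0.193 in KO (SD, n = 2). Rbm15, which recruits the writer to RNA, had 29.6 ± 11.7 CPM in WT and 79.4 ± 11.1 in KO. The readers Ythdf2 and Ythdc1 had log2 fold changes of 1.18 (SE 0.30) and 1.13 (SE 0.39). Mettl3, the catalytic subunit, differed by -0.38 (SE 0.37), and its exons overlap those of Tox4 on the opposite strand over 933 bases. The demethylases Alkbh5 and Fto differed by 0.02 and -0.09. Virma, Zc3h13, Rbm15b, Cbll1, Mettl16, Ythdf1, Ythdf3, Ythdc2, Igf2bp1, Igf2bp2, Igf2bp3 and Hnrnpa2b1 lay between -0.31 and 0.54. None of the 20 genes passed the edgeR threshold over all genes, and 2 were higher and 2 lower adjusted over the list alone. The list had a median of -0.05 while its mean and its camera test were positive (adjusted p = 0.784). It passed the fry test for change in either direction (adjusted p = 0.0313). The list holds Mettl14, by which the embryos were classed, so the fry result and the count of lower members were partly set by the classing. No list test was run without Mettl14.

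**Figure D1:**
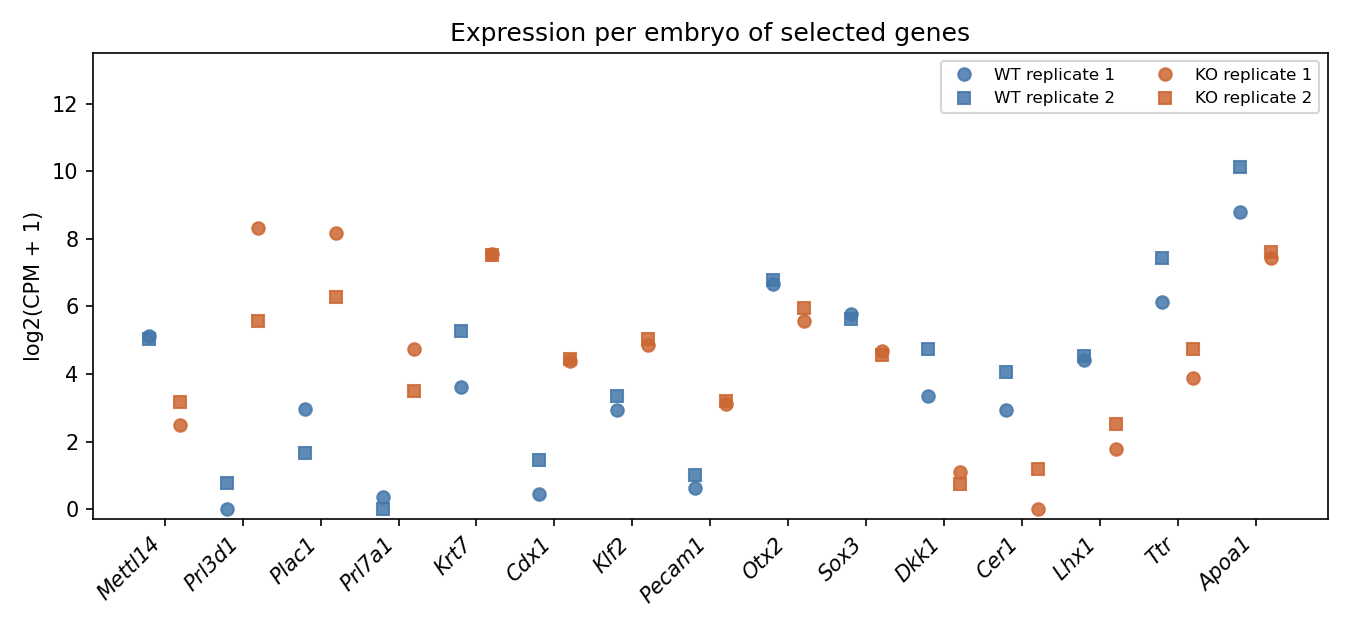
Expression of 15 genes in each embryo as log2(CPM + 1), with WT embryos in blue and KO embryos in orange, replicate 1 as circles and replicate 2 as squares. Mettl14 is at 34.0 and 31.6 CPM in WT and at 4.63 and 8.04 CPM in KO, and both embryos of each group lie apart from the other group for every gene shown. The genes were picked among those named for small p, and the embryos were classed by Mettl14, so this separation largely follows from the choice.

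The genes with the smallest p among those higher in KO included trophoblast genes. Prl3d1, placental lactogen of trophoblast giant cells, had 0 and 13 counts in the WT embryos and 6826 and 1297 in the KO embryos (log2 fold change 8.98, SE 1.34). Plac1, a placental gene on the X chromosome, had 4.46 ± 3.28 CPM in WT and 182 ± 150 in KO (SD, n = 2), and Prl7a1, of the prolactin family, differed by 6.92 (SE 1.07). Cdh5, the cadherin of endothelial junctions, had 0 counts in both WT embryos and 37.1 and 8.43 CPM in KO, at least 248-fold higher. The cytokine gene Il24 was also at 0 in WT and at least 81.5-fold higher in KO. Entpd1, an ectonucleotidase, differed by 4.50 (SE 0.61), Orai1, the pore of the store-operated calcium channel, by 2.65 (SE 0.39), and Tcf15, a bHLH factor, by 2.60 (SE 0.42). Anxa1, Serpinb6c, Il23a and the carbonyl reductase gene Cbr3 completed the 12, at 6.56, 4.06, 3.35 and 2.95. Prl3d1 has close copies among prolactin genes and Serpinb6c among serpins, so their counts are uncertain.

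Among genes lower in KO, Irs4, an insulin receptor substrate, had 29 ± 4.85 CPM in WT and 2.76 ± 0.302 in KO (SD, n = 2; log2 fold change -3.39, SE 0.46). Dkk1, a secreted WNT antagonist of the anterior visceral endoderm, differed by -4.27 (SE 0.70), and Hesx1, a homeobox repressor of the anterior embryo, by -3.70 (SE 0.64). Mttp, which loads lipid onto apolipoprotein B, differed by -2.75 (SE 0.53), and Stard4, a sterol carrier, by -1.93 (SE 0.37). Kis2, Dcn (decorin), Hist1h3d, Tmem186 and the surface glycoprotein gene Cd24a differed by -4.46, -3.54, -3.25, -2.48 and -2.09. Exons of Mttp and Tmem186 overlap Trmt10a and Pmm2 on the opposite strand over 457 and 39 bases.

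None of these genes passed the threshold of the main test. By edgeR, 0 genes were higher and 0 lower in KO, the smallest adjusted p was 0.245, and 1217 genes had an unadjusted p under 0.05 (738 higher, 479 lower) where chance gives 778. DESeq2 called 150 higher and 90 lower, among them all 24 genes given by smallest p, Mettl14 included, and limma-voom called 0; on simulated data DESeq2 made 37.4 false calls per draw and edgeR 9.6. Leaving out WT replicate 1 gave 17 higher and 26 lower by edgeR, without WT replicate 2 there were 14 and 1, without KO replicate 1 133 and 209, and without KO replicate 2 59 and 16. Both KO embryos lay outside the WT range on one side for 38.2% of genes, where chance gives 33.3% for 2 against 2.

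Genes linked to the naive state, found in the inner cell mass before implantation, had higher values in KO for 14 of 18 tested genes. Their median log2 fold change was 0.39. The median difference from WT replicates 1 and 2 was 1.03 and 0.69 for KO replicate 1, but 0.15 and 0 for KO replicate 2. For the extraembryonic ectoderm list these differences were 1.21 and 0.51, and 0.32 and -0.48. Esrrb is in both lists, and whole embryos cannot show which tissue a difference in the naive list comes from. Klf2, a Kruppel-like factor of naive cells, had 7.98 ± 1.78 CPM in WT and 29.9 ± 2.77 in KO (SD, n = 2; log2 fold change 1.90, SE 0.42). Pecam1, an adhesion molecule of the inner cell mass and of endothelium, had 0.773 ± 0.343 CPM in WT and 8 ± 0.36 in KO, and Tet2, a DNA demethylation enzyme, differed by 1.53 (SE 0.58). Dppa3, a germline and naive-state gene, had lower values in KO (-1.41, SE 0.55). The list stood at camera adjusted p = 0.0521, and at adjusted p = 0.848 with an estimated correlation; 0 members passed over all genes and 2 were higher adjusted over the list alone. Without KO replicate 2 the median was 0.84 (adjusted p = 0.00363), without WT replicate 2 0.74 (0.0291), and without KO replicate 1 0.24 (0.619).

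Genes of the primed epiblast had a median of -0.17, with 12 of 19 lower in KO. Otx2, a homeobox factor of the formative epiblast, had 106 ± 6.67 CPM in WT and 53.8 ± 10.3 in KO (SD, n = 2, log2 fold change -0.97, SE 0.33). Otx2 is also in the distal and anterior visceral endoderm list, and whole embryos cannot show which tissue its difference comes from. Sox3, an SRY-box factor, had 51.5 ± 3.97 CPM in WT and 23.7 ± 1.53 in KO, the de novo methyltransferase gene Dnmt3b differed by -0.72 (SE 0.29), and Cldn6, a tight junction gene, by -1.09 (SE 0.41). Camera gave this list an adjusted p of 0.422, with 0 members past the threshold over all genes or adjusted over the list alone. Without KO replicate 2 the adjusted p was 0.0467 at a median of -0.19, and without KO replicate 1 the median was -0.03. The core pluripotency list, shared by both states, had a median of -0.12 (adjusted p = 0.724): Lin28b, a let-7 inhibitor, differed by -1.15 (SE 0.41), Sox2 by 0.80 (SE 0.41), Epcam by -0.44 (SE 0.28) and Lin28a by -0.51 (SE 0.43). Its median was positive without KO replicate 1 (0.01), KO replicate 2 (0.17) or WT replicate 1 (0.12).

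Primitive streak and mesoderm genes had values in both directions. Cdx1, a caudal-type homeobox gene, had 1.06 ± 0.997 CPM in WT and 20.3 ± 0.845 in KO (SD, n = 2; log2 fold change 4.24, SE 0.74). Lhx1, a LIM homeobox gene also of the anterior visceral endoderm, had 21.3 ± 1.42 CPM in WT and 3.60 ± 1.61 in KO. Gsc and Fgf8, genes of the streak and its organizer, differed by -1.78 (SE 0.58) and -1.35 (SE 0.45). Of 13 tested members 0 passed over all genes, while 2 were higher and 3 lower adjusted over the list alone, and the median was 0.28 (camera adjusted p = 0.446). Without KO replicate 1 or 2 the median was -0.09 or -0.31.

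Visceral endoderm genes had lower values in KO for 27 of 29 tested members, with a median of -1.78. Ttr, the thyroid hormone carrier, had 121 ± 73.8 CPM in WT and 19.7 ± 8.48 in KO (SD, n = 2), and Apoa1, an apolipoprotein, 775 ± 472 and 183 ± 15.1. Apob, the lipoprotein backbone, differed by -2.64 (SE 0.52) and Spink1, a trypsin inhibitor, by -2.33 (SE 0.48). In the distal and anterior visceral endoderm, which patterns the epiblast, 8 of 9 genes were lower (median -1.33). Besides Dkk1 and Lhx1 they included Cer1, a NODAL and BMP antagonist, with 113 and 296 counts in WT and 0 and 35 in KO, and the WNT receptor gene Fzd5 (-2.21, SE 0.51). With the preset correlation camera gave adjusted p = 5.03e-09 and 0.000116 for these lists, and adjusted p = 0.848 for each with an estimated correlation. The estimated correlations between members were 0.766 and 0.365, far above the preset 0.01. The preset test thus treats members that move together as nearly independent, and its p-values are too small. No member passed over all genes, and 16 and 5 members were lower adjusted over the list alone. None of the 29 lists passed the directional fry test, and the distal and anterior list passed the one for change in either direction (adjusted p = 0.0431).

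The mean log2 CPM of the visceral endoderm list was 3.78 and 5.34 in the WT embryos and 2.86 and 3.25 in the KO embryos, so that the WT embryos differed by more than WT replicate 1 and the KO embryos. Without WT replicate 2 the median was -0.66 (adjusted p = 0.00912) for this list and -0.90 (0.0115) for the distal and anterior list. The latter stood at -2.11 without KO replicate 2.

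**Figure D2:**
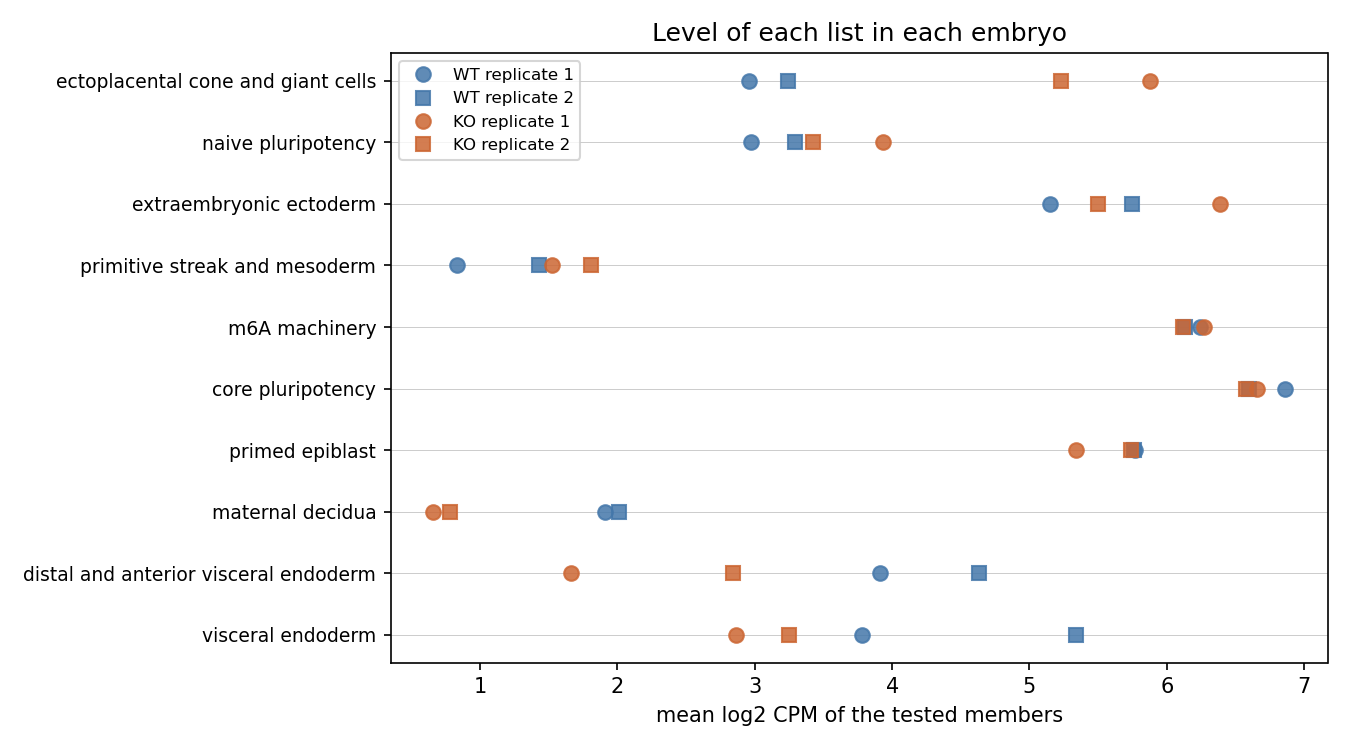
Mean log2 CPM of the tested members of 10 gene lists in each embryo, WT in blue and KO in orange, replicate 1 as circles and replicate 2 as squares. The visceral endoderm list is at 3.78 and 5.34 in WT and 2.86 and 3.25 in KO, and the ectoplacental cone and giant cell list at 2.96 and 3.24 in WT and 5.88 and 5.23 in KO.

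The ectoplacental cone and giant cell list, for differentiated trophoblast, had 7 of 21 genes tested, and 6 of them had higher values in KO (median 1.11). Besides Prl3d1 and Plac1 these included Hand1, a bHLH factor of giant cells, with 206 ± 78.8 CPM in WT and 494 ± 35.4 in KO (SD, n = 2), and Phlda2, an imprinted regulator of placental growth, with 241 ± 61.0 and 520 ± 148. Camera gave adjusted p = 0.00137 with the preset correlation and adjusted p = 0.848 with an estimated one (unadjusted camera p = 0.0594). The estimated correlation between members was -0.033, below the preset 0.01. By that estimate, which rests on 4 embryos, members that move together do not account for the gap between these forms of the test. No member passed over all genes, and 4 were higher adjusted over the list alone. The extraembryonic ectoderm list, for trophoblast progenitors, had a median of 0.31 over 26 genes (adjusted p = 0.0811, and adjusted p = 0.848 with an estimated correlation). It passed by voom (0.30, adjusted p = 0.0104), DESeq2 statistics (0.000751) and with no low-count filter (0.35, 0.0233), and without WT replicate 2 (0.99, 0.00553) or KO replicate 2 (0.62, 9.72e-05), and stood at -0.13 without KO replicate 1 (0.987). Its keratin genes Krt7 and Krt8 differed by 2.91 (SE 0.56) and 1.24 (SE 0.36) and Gata3, a trophoblast factor, by 1.51 (SE 0.47). Among parietal endoderm genes (median 0.00, adjusted p = 0.242, and 0.77 and 0.00698 without WT replicate 2), thrombomodulin, Thbd, had 0 counts in both WT embryos and 122 and 50 in KO, at least 41.7-fold higher. Snai1 differed by 1.63 (SE 0.55), Nid1 by 1.01 (SE 0.57), and Srgn had 56.9 and 318 CPM in WT and 58.9 and 53.2 in KO.

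Markers of the maternal decidua, the uterine tissue around the embryo, had a median of -0.84 over 10 tested genes (camera adjusted p = 0.0338, and adjusted p = 0.848 with an estimated correlation), with 3 lower adjusted over the list alone. The estimated correlation between members was -0.088, below the preset 0.01. Hoxa10, a uterine homeobox gene, had 15 and 93 counts in WT and 0 in both KO embryos, at least 49.5-fold lower. The collagen gene Col1a2 had 37 and 32 counts in WT and 0 and 1 in KO, and Pgr, the progesterone receptor gene, differed by -1.99 (SE 0.97). With at least 50 counts required in 2 libraries the median was 0.03, and without WT replicate 1 it was 0.21 (adjusted p = 0.422); the list did not pass without any one of the 4 libraries, nor by voom (adjusted p = 0.14). Of blood and immune markers only 4 were tested (median 0.34, adjusted p = 0.446): Cd74, Cd52, H2-Eb1 and Alas2 had means of at most 1.93 CPM in either group.

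**Figure D3:**
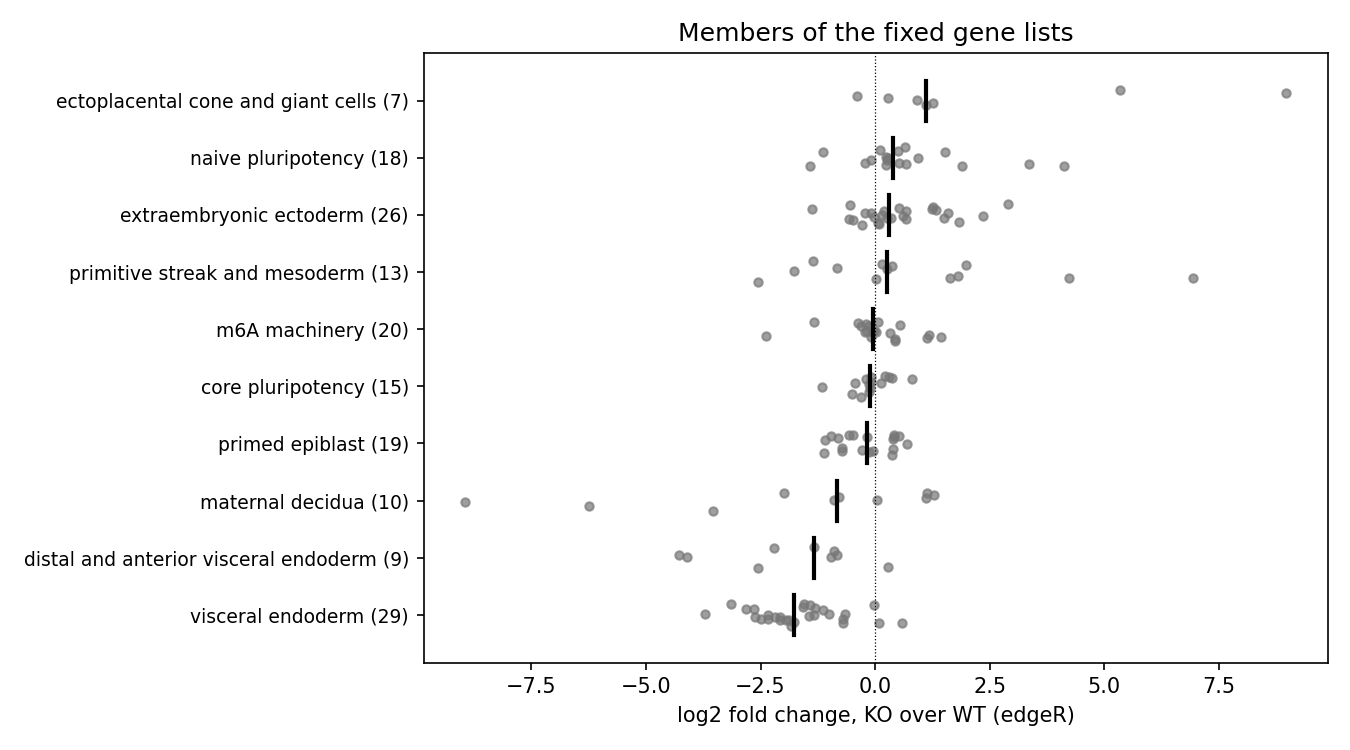
Log2 fold change of KO over WT by edgeR for each tested member (grey points, spread vertically at random) of 10 gene lists, with the number tested in parentheses and the list median as a black bar. Medians run from -1.78 for the visceral endoderm list to 1.11 for the ectoplacental cone and giant cell list.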

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

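The removal of GC and length trends, with and without the replicate block, was chosen after seeing the data; the other alternatives were fixed before, but the form of the list tests under voom and DESeq2 was set after first results. No gene passed in the main fit, with voom, RLE scaling, library totals, the filter of at least 50 counts in 2 libraries or the GC and length trend removed. DESeq2 gave 150 higher and 90 lower, no low-count filter 157 and 101. Leaving out 1 library gave 14 to 133 higher and 1 to 209 lower; of the 342 calls without KO replicate 1, 115 were unnamed genes or pseudogenes. All 24 genes given by smallest p had the sign of the main fit under each of the 13 alternatives. The rule had required both KO embryos to lie on the same side of both WT embryos. The stable sign was therefore largely fixed by the choice of genes. Mettl14 ran from -2.81 to -1.95 with 1 library left out, and passed at -2.36 with DESeq2 and no low-count filter alike, and without KO replicate 2. Lists past the threshold numbered 4 in the main fit, 9 with DESeq2 statistics, 7 with voom, 0 with an estimated correlation and 4 to 10 with 1 library left out. The visceral endoderm, distal and anterior visceral endoderm, and ectoplacental cone lists passed under each of the 13 alternative fits, but not with the estimated correlation. Extraembryonic ectoderm, proliferation, immediate early and imprinted lists also passed with DESeq2 and voom. With no low-count filter extraembryonic ectoderm (0.35), p53 targets (0.17) and immediate early genes (0.41) passed. Mitochondrially encoded genes passed at 0.76 with the trend removed and at 0.69 with the block as well. The naive list passed at 0.38 with DESeq2 statistics and also with RLE scaling, and at 0.49 with the trend removed, and ran from 0.24 to 0.84 with 1 library left out; the primed list ran from -0.23 to -0.03.

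The labels do not say that a replicate number marks a shared litter or day, so the samples share only a number. Across genes the difference between WT replicates correlated at 0.329 with that between KO replicates. The replicate block gave 52 higher and 19 lower, and 115 and 58 with the trend removed, where Mettl14 passed at -2.17. The maternal decidua list no longer passed under the block, nor with no low-count filter (median -0.36) or voom (-1.12).

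The median of 18 lists changed sign under at least 1 alternative, and 1 of these lists, maternal decidua, passed in the main fit; the cause was not tested. With 1 library left out, medians ran from -1.41 to 0.21 for maternal decidua, -0.13 to 0.18 for m6A machinery, -0.26 to 0.17 for core pluripotency, -0.31 to 0.99 for primitive streak and mesoderm, -0.13 to 0.99 for extraembryonic ectoderm, -0.40 to 0.77 for parietal endoderm, -0.37 to 0.73 for blood and immune, 0.00 to 0.47 for p53 targets, 0.24 to 0.63 for interferon response, -0.37 to 0.44 for FGF and ERK targets, -0.47 to 0.47 for WNT targets, -0.10 to 0.07 for integrated stress, -0.33 to 0.07 for glycolysis and hypoxia, -0.38 to 0.15 for cholesterol synthesis, -0.05 to 0.05 for DNA methylation, -0.36 to 0.28 for epithelial and lumen, -0.13 to 0.03 for ribosomal proteins and -0.33 to 0.45 for mitochondrially encoded genes. Lists that kept their sign ran from -2.33 to -0.66 for visceral endoderm, -2.11 to -0.90 for distal and anterior visceral endoderm, 0.90 to 1.41 for ectoplacental cone, -0.51 to -0.27 for germline, 0.10 to 0.37 for apoptosis regulators, -0.43 to -0.15 for proliferation, 0.08 to 0.21 for BMP and NODAL targets, 0.20 to 0.67 for immediate early and -1 to -0.16 for imprinted genes. Germline genes were at -0.52 with voom and with the block, -0.58 with at least 50 counts in 2 libraries, -0.08 with the trend removed and -0.10 with the block as well, where immediate early genes were at 0.19. Signs turned in maternal decidua (0.03) and interferon response (-0.05) with at least 50 counts in 2 libraries, in epithelial and lumen with library totals (0.02) and with no low-count filter (0.01), and in parietal endoderm (-0.03), blood and immune (-0.21) and WNT targets (-0.16) with no low-count filter. Interferon response was at -0.15 and FGF and ERK targets at -0.05 with voom, and at -0.15 and -0.04 with the replicate block. With the GC and length trend removed, m6A machinery was at 0.02, parietal endoderm at -0.09 and DNA methylation at 0.03; with the block as well these were 0.01, -0.07 and 0.02, interferon response -0.05 and FGF and ERK targets -0.06.

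Of 140 genes named by the rule besides Mettl14, 14 changed sign, none of them past the threshold in the main fit. With the trend removed Ythdf3 was at 0.16 and Hnrnpa2b1 at 0.13, and with the block as well at 0.16 and 0.12. With 1 library left out, Zc3h13 ran from -0.28 to 0.41, Rbm15b from -0.55 to 0.13, Fto from -0.27 to 0.14, Ythdf3 from -0.58 to 0.21, Ythdc2 from -0.90 to 0.40, Igf2bp1 from -0.08 to 0.04, Hnrnpa2b1 from -0.17 to 0.16, Lin28a from -1.14 to 0.01, Nid1 from -0.14 to 1.67, Alas2 from -0.61 to 1.84, H2-Eb1 from -3.28 to 0.39, Tsix from -2.20 to 0.29, mt-Cytb from -0.06 to 0.45 and mt-Rnr1 from -0.48 to 1.19.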

Other observations

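Nearly every test of an explanation below was chosen after its result was seen. The bound for a single X chromosome and the test of long transcripts in KO replicate 2 were set before. Among germline genes (median -0.30, camera adjusted p = 0.129, -0.51 and 0.0126 without KO replicate 2, -0.58 and 0.0587 with at least 50 counts in 2 libraries, and -0.08 and 0.657 with the GC and length trend removed), Sycp3, of the meiotic chromosome axis, had 19.4 ± 1.59 CPM in WT (SD, n = 2) and 4.49 and 4.48 in the KO embryos, and its exons overlap Chpt1 on the opposite strand over 660 bases. Hormad1, of the same axis, differed by -0.92 (SE 0.36), and Rpl10l, a ribosomal protein gene copy of the testis, by 1.63 (SE 0.41). Imprinted genes had a median of -0.55 (adjusted p = 0.130), -1 (0.025) without KO replicate 1, -0.33 without WT replicate 1 and -0.16 without KO replicate 2, and passed by voom (0.0198) and DESeq2 statistics (0.0269): Peg10, a retrotransposon-derived placental gene, differed by -1.88 (SE 0.43), and the noncoding RNAs Rian and Meg3 by -1.61 (SE 0.51) and -1.98 (SE 0.69). Immediate early and heat shock genes had a median of 0.41 (adjusted p = 0.0875), 0.67 (0.00363) without KO replicate 2, 0.20 without WT replicate 1 and 0.24 without KO replicate 1, and passed by voom (0.0232), DESeq2 statistics (0.00282) and with no low-count filter (0.0476). The list had Egr1 at 72.2 CPM in KO replicate 1, 18.8 in KO replicate 2 and 4.42 and 2.40 in WT. Fos, Junb and the chaperone gene Dnajb1 differed by 2.04, 1.23 and 1.32. For p53 targets (median 0.13, adjusted p = 0.132), Cdkn1a, an inhibitor of the cell cycle, had 78.7 CPM in KO replicate 2 against 26.5 in KO replicate 1 and 22.7 and 14.6 in WT, and Phlda3 had 241 against 71.2, 49.5 and 65.2. Pmaip1, a pro-apoptotic target, went the other way (-1.85, SE 0.42), and the p53 list stood at 0.47 (0.048) without KO replicate 1, 0.38 without WT replicate 1, 0.34 without WT replicate 2 and 0.00 without KO replicate 2, and passed with no low-count filter (0.0476).

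Proliferation genes had a median of -0.36 (adjusted p = 0.117), -0.43 (0.0126) without WT replicate 1, -0.39 (0.0378) without KO replicate 2 and -0.15 (0.905) without WT replicate 2, and passed by voom (0.0142) and DESeq2 statistics (0.0127). The list had Cdc20, an activator of mitotic exit, at -1.04 (SE 0.36) and Ccnd2, a G1 cyclin, at 1.94 (SE 0.47). Among FGF and ERK targets (median 0.31, adjusted p = 0.602, but -0.37 without KO replicate 1, -0.05 by voom and -0.04 with the replicate block), Myc had 112 ± 36.1 CPM in WT and 285 ± 73.3 in KO (SD, n = 2). Dusp4 went the other way (-1.09, SE 0.48), and of the 17 members 9 were higher and 8 lower. Among BMP and NODAL targets (median 0.29, adjusted p = 0.416, and 0.08 to 0.21 with 1 library left out), Bambi and Msx1 differed by 1.18 (SE 0.37) and 1.22 (SE 0.45). WNT targets had a median of 0.13 while their mean and test were negative (adjusted p = 0.771), with Cdx1 at 4.24 and Dkk1 at -4.27. Medians and adjusted p were 0.14 and 0.420 for apoptosis regulators (0.10 to 0.37 with 1 library left out), 0.20 and 0.473 for interferon response, -0.15 and 0.758 for integrated stress, -0.16 and 0.463 for glycolysis and hypoxia, and -0.07 and 0.223 for cholesterol synthesis, which passed without KO replicate 2 (-0.38, 0.00395). They were -0.07 and 0.944 for DNA methylation, whose mean was positive, and 0.00 and 0.624 for epithelial and lumen genes. Ribosomal protein genes stood at -0.07 and 0.422, and mitochondrially encoded genes at 0.08 and 0.717, and at 0.76 (0.00078) with the GC and length trend removed, an alternative added after the data were seen. The lists past the fry test for change in either direction were m6A machinery, naive pluripotency, distal and anterior visceral endoderm, maternal decidua, germline and WNT targets, 6 of the 29. The m6A machinery list holds Mettl14, by which the embryos were classed. With an estimated correlation none of the 29 passed camera (smallest adjusted p = 0.848). That form of the test also called the simulated shift of -1.5 in 0 of 5 draws. Its failure to pass is therefore not evidence against a shift of any list.

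Trophoblast giant cell genes had higher and visceral endoderm genes lower values in KO. Maternal decidua carried along with trophoblast would raise its markers; their median was -0.84, but with 4 higher and 6 lower its 95% bootstrap interval ran from -3.57 to 1.12, and it was 0.21 without WT replicate 1, -0.08 without WT replicate 2, -0.11 without KO replicate 2 and -1.41 without KO replicate 1, so this stays open. A larger share of all trophoblast stays open. The giant cell median exceeded that of extraembryonic ectoderm by 0.80, with a 95% bootstrap interval of -0.32 to 5.19. First versions of this test and that of decidua, which left out the spread of the list members, had argued against both explanations. Both intervals resampled list members, not embryos, so they do not measure the spread between embryos. Hand1 is in both trophoblast lists, which were resampled separately. A visceral endoderm share that varies between embryos of 1 genotype may contribute, since the WT embryos differed by 1.57 and the lower of them from the KO mean by 0.69. The KO embryos differed by only 0.29 from each other. KO replicates 1 and 2 differed from WT replicate 2 by -2.55 and -2.15, and from WT replicate 1 by -0.89 and -0.40. An effect of genotype on either tissue stays open too.

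Genes with few exon junctions for their length had higher values in KO, a pattern found among 70 correlations of 10 transcript features with 7 contrasts, and after models on exon number had been tried: single-exon genes had a median of 0.10, genes of 2 to 3 exons 0.26 and genes of over 20 exons -0.10 (0.26 for KO replicate 1 over WT replicate 2, and -0.33 and -0.43 within groups), and junction density correlated at -0.175 with the fold change across 8332 genes, which are not independent replicates. Genomic DNA would raise olfactory and vomeronasal receptor CPM, which was below both WT embryos (25.1 and 8.05) in KO replicate 2 (4.91) but between them in KO replicate 1 (12.2), where it stays open; a first version on group means had argued against it in both. With linear terms for GC content, log length and expression in the model the coefficient of junction density was -0.119, from -0.163 to -0.07 in the 4 KO to WT pairs. It was -0.041 between the WT and -0.051 between the KO embryos. All values within groups given here are replicate 2 minus replicate 1. That order is arbitrary, so their size can be compared with the KO to WT pairs but their sign cannot. GC content itself correlated at 0.208 with the fold change. Linear terms thus did not remove the pattern, but they cannot exclude trends of another shape, so this stays open. Loss of m6A could stabilise such transcripts, since junctions keep m6A off nearby sites, but the coefficient of m6A motifs far from junctions exceeded that of near motifs by 0.067, from 0.003 to 0.13 in the 4 KO to WT pairs, against 0.06 and 0.065 between embryos of 1 group. That explanation and a different makeup of tissues stay open.

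Xist, the RNA that silences an X chromosome, had 169 counts in KO replicate 2 (6.16 CPM) against 202, 59.9 and 69.7 CPM in the other 3 embryos, and 7 Y-linked genes together had at most 5 counts in any embryo. Weak recovery of long transcripts, of the size seen in genes with at least 10 kb of exons, does not account for it. Xist lay 3.94 log2 units lower (-3.94) where the lowest 2.5% of these 880 genes began at -2.01. Their exons were merged over all isoforms, so their transcripts can be shorter than that. A steeper loss in longer single transcripts is therefore not excluded. With both X chromosomes active, X-linked genes would stand above autosomal ones. The difference was 0.079, against 0.03, -0.188 and 0.037 in the other embryos, each embryo being set against the mean of the others. It was the highest of these values, but WT replicate 2 deviated by more in the other direction, so this stays open. A first version without that comparison had argued against it. A single X chromosome may underlie it: 8 genes known to escape silencing lay at -0.52 relative to other X-linked genes, and at -0.38 without Ftx and Jpx, neighbours of Xist. The value met the bound of -0.3 set beforehand, which alone would have favoured a single X chromosome, and was the lowest of any embryo. A comparison with the spread of the other embryos was added to that bound later. WT replicate 1 deviated by more the other way (0.59 and 0.39), and such values, each against the mean of the other embryos, are not independent. The explanation therefore stays open.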
